A study of Trypanosoma brucei with 12 samples.

How the data were processed

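Total RNA of Trypanosoma brucei was taken from the procyclic form, which lives in the midgut of the tsetse fly, and from the bloodstream form, which lives in the mammalian host. RibOxi-seq maps 2'-O-methylated nucleotides (Nm) in RNA. RNA is fragmented at random, and periodate oxidation with elimination removes the last nucleotide of fragments whose 3' end carries free 2' and 3' hydroxyls. A 2'-O-methyl group blocks the oxidation, so that fragments ending at an Nm keep their end and can be ligated to an adapter. Each stage had 3 oxidised libraries and 3 non-oxidised control libraries, and the labels gave passage 7, 7 and 9 for procyclic replicates 1, 2 and 3 and passage 5, 8 and 8 for bloodstream replicates 1, 2 and 3. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

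For each library the authors deposited 1 value for each of 8500 positions, 370000 to 378499 on the sequence that the files name Tb427_02_v4. How these values were made, including the aligner and the trimming, was not given in the sources used here. The values are whole numbers, but they were treated as a score and not as read counts. Over the 12 libraries, 771 positions held exactly 50 and 6 positions held exactly 49, and values from 1 to 49 were multiples of 3 more often than the 33.3% of an even spread (34.6% to 60.7% by library). The deposited score was therefore given as score per 1000000 of the library total (SPM), and count models were not used. For each position and stage, the deposited tables of comparisons give, per the file headers, a mean normalised signal (baseMean) and a log2 fold change with its standard error. They also give a test statistic and a p-value with its adjusted p-value. DESeq2 is named in the submitters' processing notes without a version. The deposited baseMean signal was recovered from the deposited scores by median-of-ratios scaling at 6230 of 6230 procyclic and 6225 of 6225 bloodstream positions (relative tolerance 0.001), so those tables were computed on the same scores. The authors also deposited a relaxed and a stringent list of sites per stage with log2 fold change, adjusted p-value and signal. The header of each list states an adjusted p of 1e-05, whereas the members of all 4 lists were exactly the positions with an adjusted p of at most 1e-06 in the deposited tables (0 mismatches). The log2 thresholds in the headers held, with 6 for both stringent lists, 3 for the relaxed procyclic list and 4 for the relaxed bloodstream list.

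Positions with values fell into 8 blocks when gaps of up to 10 positions were bridged. The blocks were named by their order and length from the rRNA genes of the assembly ASM244v1, another build, of which only order and length were used. Each block was 7 to 17 nucleotides shorter than the median of 9 annotated units. The small subunit rRNA (SSU) covered 370063 to 372299, 5.8S rRNA 372650 to 372809, large subunit rRNA (LSU) alpha 373409 to 375230 and LSU beta 375726 to 377195. The 4 small LSU rRNAs covered 375434 to 375634, 377349 to 377514, 377854 to 377916 and 378252 to 378371, and were numbered 1 to 4 in this order. The trypanosome LSU rRNA is cleaved into these pieces. No sequence of this build was used, so the base at each site and conserved landmark loops were not analysed here.

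The design fixed before the data were examined assumed counts and named a count model. Because the values are scores, limma 3.58.1 in R 4.3.3 was used on log2 of the scaled SPM plus a pseudocount of 10. Scaling factors were trimmed means of log ratios (30% trimmed on the ratio, 5% on the level). Positions entered a fit with at least 20 scaled SPM in at least 3 of its libraries. Fits used group means, an empirical Bayes trend and robust variances, and the Benjamini-Hochberg adjusted p threshold was 0.05. Fold changes on this scale understate changes of low positions. Each stage was fitted alone. The difference of the oxidation effect between stages (interaction) used all 12 libraries, and stage comparisons in controls or in oxidised libraries used 6. Positive stage values mean higher in the bloodstream form. Counts per block used two-sided Fisher's exact tests, and shares used two-sided exact permutation tests of 3 against 3 libraries, for which 0.1 is the smallest p. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the remaining steps.

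The named positions followed a rule set before the data were examined. Per stage these were the 20 largest rises among positions with adjusted p under 0.05, a mean of at least 100 SPM in the oxidised libraries and every oxidised library above every control, and the 5 largest falls by the mirrored rule with 100 in the controls. Stage differences were to give up to 10 positions in each direction among interaction calls, and stringent sites listed for 1 stage gave the 10 with the largest absolute interaction. By chance, 10% of positions show no overlap of 3 against 3 libraries. Position lists whose rules were fixed at the same time were the deposited lists, the direct 5' and 3' neighbours of stringent sites, the 100 highest positions in the controls of each stage and the blocks. The neighbour lists as used left out positions that were themselves stringent.

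The procedure was tested on simulated scores, with weights of 50 and 200 changed positions per comparison. At a log2 change of 4 it recovered 83.6% of changed positions for the procyclic comparison (4218 positions tested), 84.4% for the bloodstream comparison (4320), 100% for controls (4285), 81.8% for oxidised libraries (2130) and 53.0% for the interaction (4705). At a log2 change of 2 it recovered 22.6%, 51.5%, 84.1%, 8.33% and 10.4%, and at a log2 change of 1 it recovered 0%, 2.99%, 19.4%, 3.70% and 0%. At most 3.79% of calls in these simulations fell on unchanged positions. All simulated libraries of a comparison shared 1 set of means, with no offset of replicate 3. Changes went in both directions, without the shift of score to few positions that oxidation brought. Recovery and false calls in the real fits may therefore differ from these values and were not measured.

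The number of reads behind a score is unknown. If every read carried a weight of 50, the library totals would correspond to at least 14021 reads in procyclic oxidised replicate 3 and 486374 reads in bloodstream control replicate 3, and a single such read is worth 71.3 and 2.06 SPM in these libraries. No interval for counting error was therefore given. Alternatives changed the scaling, the filter, the threshold, the pseudocount, the blocks and the libraries used. DESeq2 was not run, although planned, because the values are not counts. The planned filter of 50 reads and glmTreat were not run either, and a filter of 100 SPM and limma's treat stood in for them.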

Results

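Ends of rRNA fragments were scored at each nucleotide of 1 rRNA unit in 12 RibOxi-seq libraries, 3 oxidised and 3 control libraries from each of the procyclic and bloodstream forms of Trypanosoma brucei. The unit held SSU rRNA, 5.8S rRNA, LSU alpha and beta rRNA and 4 small LSU rRNAs. Library total scores in controls were 15292270, 16127143 and 17660883 for procyclic replicates 1, 2 and 3 and 13237502, 13562951 and 24318696 for bloodstream replicates. Oxidised libraries were smaller, with 6549652, 5182487 and 701015 in procyclic and 1881867, 1744789 and 4187713 in bloodstream replicates. Levels are given as score per 1000000 of the library total (SPM), without the scaling factors. For the fits of oxidation, SPM were divided by factors of 2.38 to 2.65 in procyclic controls and 0.305 to 0.559 in procyclic oxidised libraries. The bloodstream factors were 2.39 to 2.69 and 0.304 to 0.470. Log2 fold changes of the fits therefore do not describe the ratio of the SPM printed beside them.

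It was first asked which positions kept their ends after oxidation, the signature of Nm. In the procyclic form, ends piled up at few positions of the SSU, 5.8S and LSU rRNAs. Position 372797, 12 nucleotides before the last scored position of 5.8S rRNA, rose from 11.7 ± 2.27 to 56103 ± 7274 SPM (SD, n = 3 per group). The fitted log2 fold change there was 13.19 ± 0.36 (SE, limma adjusted p = 9.95e-08). In SSU rRNA, position 371916 rose from 11.9 ± 11.1 to 43025 ± 4026 and position 370142 reached 12554 ± 4006 SPM (log2 12.84 ± 0.40 and 11.51 ± 0.49). In LSU alpha, position 374534 rose by 11.90 ± 0.42 on the log2 scale to 24635 ± 3973. The highest level of these sites was at position 377147 of LSU beta, with 117887 ± 9496 SPM after oxidation against 602 ± 319 in controls (log2 10.28 ± 0.38, limma adjusted p = 2.51e-07).

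The 20 named rises in the procyclic form had log2 fold changes of 9.58 to 13.19. They comprised 10 positions in SSU, 3 in 5.8S, 4 in LSU alpha and 3 in LSU beta, and all 20 were on the authors' stringent list. The 2 largest falls lay near the ends of SSU and 5.8S rRNA. At position 372297, 2 nucleotides before the last scored position of SSU rRNA, the score fell from 8462 ± 2471 to 2.54 ± 4.41 SPM (log2 -7.86 ± 0.57). Position 372805 near the end of 5.8S rRNA fell from 10238 ± 2213 to 23.8 ± 41.2 (log2 -7.14 ± 1.09, limma adjusted p = 0.00110), and 2 of the 3 oxidised libraries were at 0. Positions 370262 (log2 -5.96 ± 0.53) and 371078 (-5.39 ± 0.67) in SSU and 372736 (-5.53 ± 0.57) in 5.8S completed the 5 named falls. They lay 2037, 1221 and 73 nucleotides before the last scored position of their block.

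Of 3429 procyclic positions tested, 1273 passed the limma threshold, 542 higher and 731 lower after oxidation. With scaling by the library total alone, 207 were higher and 2966 lower, and the median log2 fold change of tested positions moved from -0.51 to -2.20. RLE scaling gave 467 higher and 1110 lower. Rises and falls are thus relative to the scaling, and 206 rises and 731 falls held under both the trimmed and the total scaling. Without control replicate 1, 2 or 3, calls were 504 (358 higher, 146 lower), 514 (360 and 154) and 569 (377 and 192), so that rises outnumbered falls, but 2670, 2660 and 2612 positions then passed the filter of 3 libraries. On the 3429 positions tested with all libraries, a choice made after the data were seen, the same runs gave 371 higher and 472 lower, 371 and 474, and 394 and 544, whereas rises were in slight excess without procyclic oxidised replicate 3 (901 and 873).

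The bloodstream form was examined for the same question, and its strongest sites lay in the same molecules. Position 371916 of SSU rRNA rose from 6.58 ± 4.29 to 34762 ± 1881 SPM (SD, n = 3 per group), a log2 fold change of 12.74 ± 0.31 (SE, limma adjusted p = 4.80e-07). Position 370142 rose by 12.43 ± 0.30 to 24953 ± 8481, and position 372797 of 5.8S rRNA by 11.91 ± 0.35 to 39262 ± 895. Position 372677 of 5.8S rRNA reached 7184 ± 362 SPM, while it was listed at 0 in all 3 controls. Position 377147 of LSU beta was called at a log2 fold change of 8.94 ± 0.84, but its oxidised libraries ranged widely, with 22966, 21506 and 138857 SPM in replicates 1, 2 and 3.

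The 20 named rises in the bloodstream form had log2 fold changes of 9.54 to 12.74, with the same distribution of 10, 3, 4 and 3 positions over SSU, 5.8S, LSU alpha and LSU beta. Of these, 15 were also among the 20 procyclic rises, and all 20 were on the authors' stringent list for this stage. The SSU end at 372297 fell from 16628 ± 5407 SPM and the 5.8S end at 372805 from 12245 ± 2953, and both were listed at 0 in all 3 oxidised libraries. The other named falls were 370262 (log2 -6.58 ± 0.37) and 372197 (-6.24 ± 0.85) in SSU and 373829 (-6.27 ± 0.55) in LSU alpha.

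Of 3226 bloodstream positions tested, 1684 passed the limma threshold, 765 higher and 919 lower. Scaling by the library total gave 253 higher and 2777 lower, with a median log2 fold change of -2.16 in place of -0.41. All 253 of these rises were among the 765. Without control replicate 1, 2 or 3, calls were 749 (553 higher, 196 lower), 744 (547 and 197) and 784 (573 and 211), and replicates 1 and 2 alone, chosen after the data were seen, gave 631 (457 and 174), so that rises outnumbered falls in each. On the 3226 positions tested with all libraries, also chosen afterwards, falls outnumbered rises in these 4 runs, with 561 higher and 755 lower, 553 and 765, 610 and 813, and 840 and 1091.

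**Figure D1:**
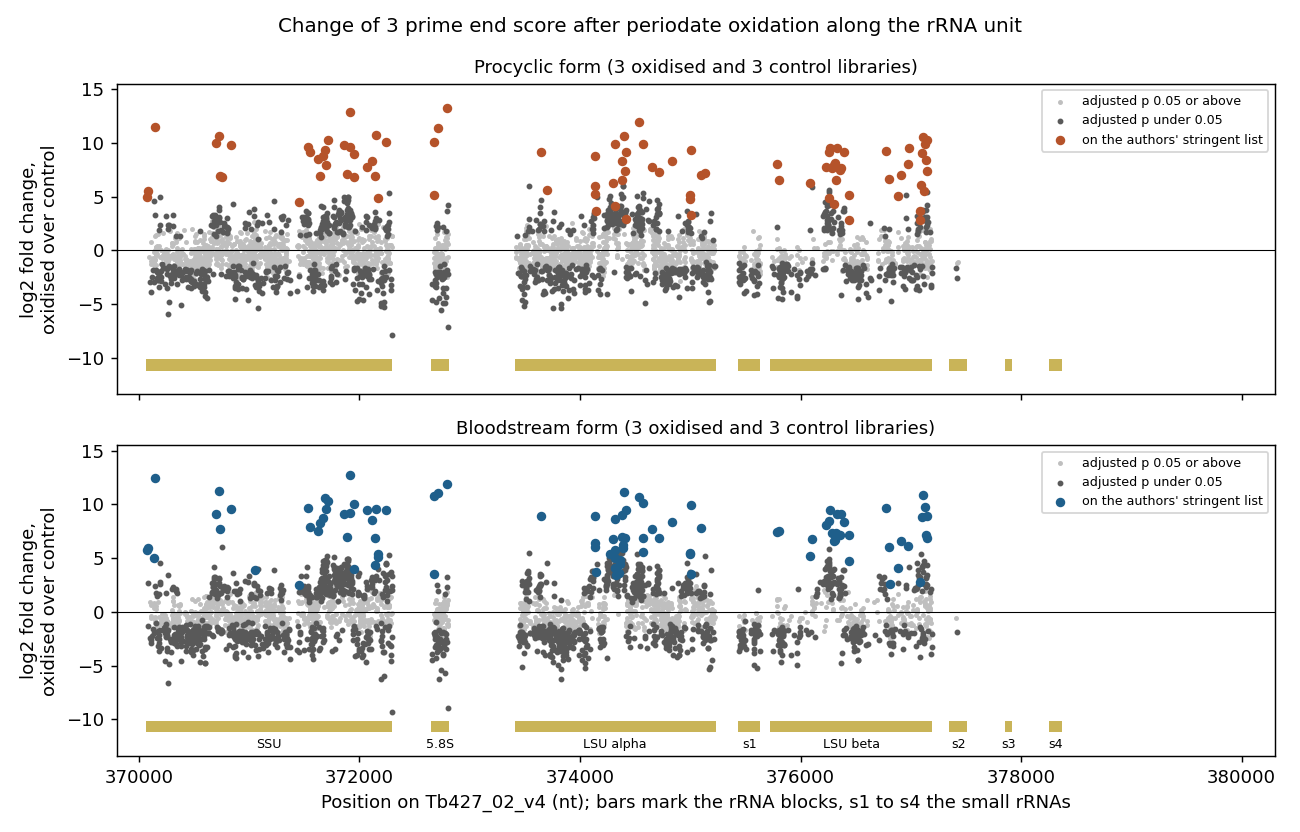
Log2 fold change of the 3' end score, oxidised over control (y axis), at each tested position of the rRNA unit (x axis, nucleotides on Tb427_02_v4) for 3 against 3 libraries of the procyclic form (top) and the bloodstream form (bottom). Coloured points are sites on the authors' stringent lists, dark points other positions with adjusted p under 0.05 and light points the remaining positions. Stringent sites lie in SSU, 5.8S, LSU alpha and LSU beta. None lies in the small rRNAs, of which numbers 3 and 4 had 0 tested positions and number 2 had 4 and 2.

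**Figure D2:**
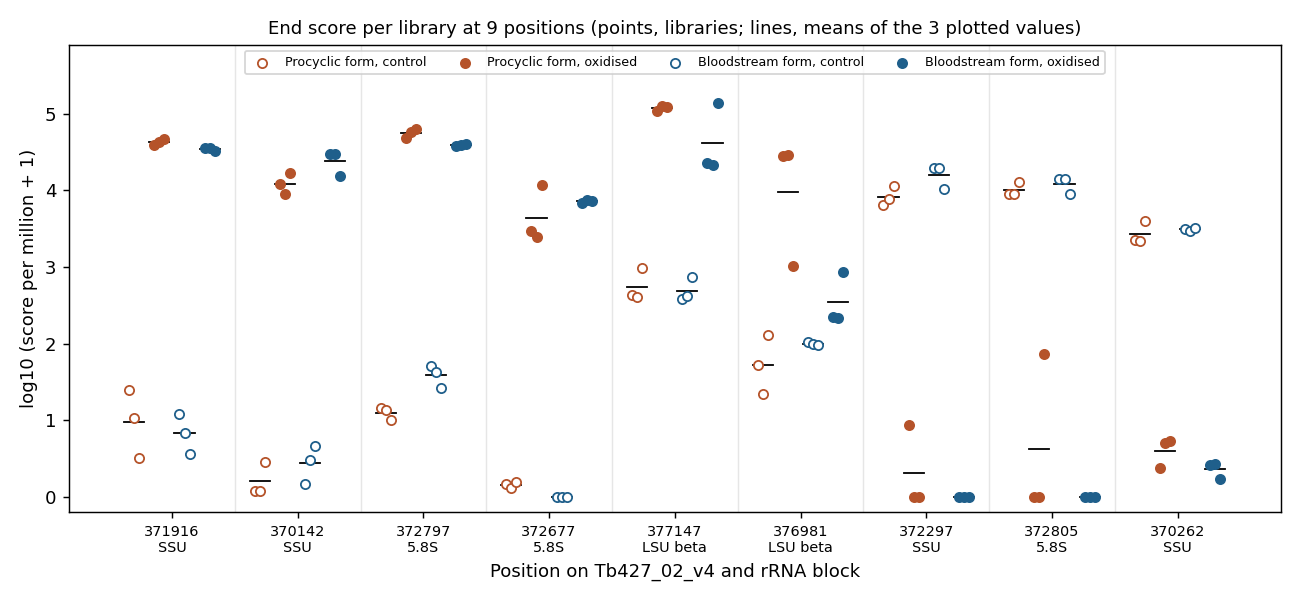
SPM plus 1 on a log10 scale (y axis) in each of the 12 libraries at 9 positions (x axis), with points for libraries, open for controls and filled for oxidised libraries, and lines for means of the 3 plotted values. The oxidised libraries lie above the controls at the first 6 positions and below them at 372297, 372805 and 370262, and at 376981 procyclic oxidised replicate 3 is at 1017 against 27664 and 29223 in replicates 1 and 2.

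The rRNA molecules differed in how many of their tested positions rose. In the procyclic form, 518 of 1470 positions of LSU beta passed the filter, 1530 of 2237 in SSU and 1182 of 1822 in LSU alpha. The bloodstream form had 464, 1460 and 1113 that passed. Shares of tested positions thus rest on unlike parts of these blocks. Over all positions of these blocks, tested or not, LSU beta had the lowest share of rises in both stages. In the procyclic form, 109 of 518 tested positions of LSU beta rose, against 14.9% elsewhere (odds ratio 1.52, Fisher's exact adjusted p = 0.00195). Falls were also more frequent there, at 157 of 518 against 19.7% elsewhere (odds ratio 1.77, Fisher's exact adjusted p = 2.27e-06). SSU had 220 of 1530, 5.8S 12 of 117 and LSU alpha 201 of 1182 positions that rose (Fisher's exact adjusted p = 0.0935, 0.170 and 0.224). Falls were less frequent in SSU, at 273 of 1530 against 24.1% elsewhere (odds ratio 0.683, Fisher's exact adjusted p = 3.41e-05). With runs of adjacent calls counted once this held (Fisher's exact adjusted p = 0.000725). SSU falls in the bloodstream form, 392 of 1460, did not pass (Fisher's exact adjusted p = 0.121). Small rRNA 1 had 0 rises among 78 tested positions (adjusted p = 1.24e-05) and 32 falls (adjusted p = 0.000224). In the bloodstream form, 295 of 1113 positions of LSU alpha rose (26.5% against 22.2% elsewhere, Fisher's exact adjusted p = 0.0210), whereas 9 of 120 did so in 5.8S (adjusted p = 1.53e-05) and 1 of 67 in small rRNA 1 (adjusted p = 4.40e-06). LSU beta had 129 of 464 (adjusted p = 0.0695) and SSU 331 of 1460 (adjusted p = 0.255). Falls in the bloodstream form were most frequent in small rRNA 1, at 47 of 67 (Fisher's exact adjusted p = 2.62e-11), and not in excess in LSU beta, at 138 of 464 (odds ratio 1.07, adjusted p = 0.590). With runs of adjacent calls counted once, the excess in LSU alpha of the bloodstream form was lost (odds ratio 0.985, Fisher's exact adjusted p = 1), while LSU beta stood out in both stages (odds ratio 1.66 and 1.60, Fisher's exact adjusted p = 0.00175 for each). With total scaling, chosen after the data were seen, 54 positions rose and 575 fell in procyclic LSU beta, 70 and 1228 in SSU and 77 and 952 in LSU alpha. Rises there stayed more frequent in LSU beta (odds ratio 1.65, Fisher's exact adjusted p = 0.0136) and became less frequent in SSU (odds ratio 0.671, adjusted p = 0.0213). In the bloodstream form, LSU beta (odds ratio 1.40, adjusted p = 0.0769), the excess of rises in LSU alpha (adjusted p = 0.0927) and the deficit in 5.8S (adjusted p = 0.118) did not pass. These tests covered 24 combinations of stage, direction and block, and neighbouring positions are not independent.

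Few positions carried most of the ends after oxidation. The 100 highest positions of a library held 83.0% ± 3.32 of the score in procyclic oxidised libraries and 29.2% ± 0.241 in controls (SD, n = 3, exact permutation p = 0.1, adjusted p = 0.126 over 24 tests). Bloodstream values were 80.2% ± 1.68 and 30.1% ± 1.72 (exact permutation p = 0.1). LSU beta held 23.9% ± 4.86 of the procyclic score after oxidation and 10.1% ± 1.60 before it, and 16.0% ± 5.20 against 9.73% ± 0.817 in the bloodstream form. Most of this difference lay at the single position 377147, which held 11.8% ± 0.950 of the procyclic and 6.11% ± 6.73 of the bloodstream oxidised score. Without it, a choice made after the data were seen, LSU beta held 12.1% ± 5.01 of the procyclic oxidised score (exact permutation p = 0.6 against controls) and 9.86% ± 1.54 against 9.67% ± 0.837 in the bloodstream form (exact permutation p = 0.8). Small rRNA 1 went from 1.65% ± 0.376 to 0.110% ± 0.0540 in the procyclic and from 1.57% ± 0.0694 to 0.0795% ± 0.0203 in the bloodstream form. With all positions of LSU beta, each of its differences and those of small rRNA 1 separated all oxidised from all control libraries at an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow.

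The authors' lists name 101 procyclic and 110 bloodstream stringent sites, of which 88 are shared. By block, the stringent sites were 32 and 35 in SSU, 4 and 4 in 5.8S, 28 and 39 in LSU alpha and 37 and 32 in LSU beta for procyclic and bloodstream forms. The small rRNAs held 0. In small rRNA 2, 4 procyclic and 2 bloodstream positions of 166 passed the filter used here. In small rRNAs 3 and 4, 0 of 63 and 0 of 120 passed in either stage. The lack of listed sites in small rRNAs 2, 3 and 4 therefore does not show a lack of Nm. The lists were chosen by the study on these libraries, so their direction is not independent evidence. Of the 101 procyclic sites, 93 were tested here and all 93 rose, also when adjusted over the list alone. Of the 110 bloodstream sites, 100 were tested and all 100 rose, also when adjusted over the list alone. Medians of the log2 fold change were 7.74 and 7.34, and with total scaling 6.06 and 5.74, with 91 and 93 sites called. The 101 sites held 62.3% ± 3.21 of the procyclic oxidised score and 0.494% ± 0.117 of the control score, and the 110 sites held 58.1% ± 4.03 and 0.593% ± 0.0612 in the bloodstream form (SD, n = 3). A further 449 procyclic and 665 bloodstream rises were not on the stringent list of their stage, which were 116 and 160 with total scaling and 224 and 398 with treat, both chosen after the data were seen.

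The relaxed lists hold 202 and 253 sites, with 156 shared, at different fold thresholds (log2 of 3 and 4). Of the relaxed sites 190 procyclic and 240 bloodstream ones rose here, all that were tested. At a log2 threshold of 3 for both stages, the authors' deposited tables gave 202 and 325 sites with 166 shared. Fold changes of the fit and of the authors' deposited tables correlated across positions at a Spearman rho of 0.983 in the procyclic (3429 positions) and 0.982 in the bloodstream form (3226 positions), with Pearson r of 0.962 and 0.956. Positions are not independent replicates, and both sides come from the same libraries.

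Direct neighbours of stringent sites were compared in the same way. Neighbours that were themselves stringent sites of the stage were left out, which can lower the share of neighbours that rose. Of 88 neighbours on each side of procyclic stringent sites, 49 on the 5' side and 27 on the 3' side did not pass the filter, which low positions pass only through their oxidised level. Without a filter, chosen after the data were seen, 35 of 87 rose on the 5' side and 13 of 88 on the 3' side (median log2 1.27 and 0.19), and 37 of 93 and 26 of 94 in the bloodstream form (1.61 and 0.49). Of 39 positions that passed on the 5' side of procyclic sites, 29 rose and 1 fell, with a median log2 fold change of 2.52. On the 3' side, 12 of 61 rose and 2 fell, with a median of 0.33. Bloodstream values were 38 of 47 on the 5' side and 27 of 64 on the 3' side, where 7 fell. Adjusted over the list alone, 31, 12, 40 and 27 rose. With total scaling, 13 rises and 8 falls were called on the procyclic 5' side and 3 rises and 38 falls on the 3' side, where the median was -1.76. The bloodstream counts were then 16 rises and 7 falls on the 5' side and 9 rises and 37 falls on the 3' side, where the median turned from 0.78 to -1.59. Among the 100 highest control positions, 67 procyclic and 71 bloodstream ones fell and 9 and 16 rose. Adjusted over the list alone, 72 and 72 fell. With total scaling, 91 and 88 fell and 3 and 4 rose. These positions were chosen by their level in the same controls, which favours falls. In the bloodstream form, whose libraries did not choose it, 73 positions of the procyclic list fell and 13 rose. Of the bloodstream list, 62 fell and 13 rose in the procyclic form.

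Oxidation effects were next compared between the life stages. Fold changes of the stages correlated across 2939 positions tested in both at a Pearson r of 0.904 and a Spearman rho of 0.840. Of 482 procyclic and 673 bloodstream rises among these positions, 422 were shared, against 110.4 for independent lists, and no position rose in one stage and fell in the other. The interaction was called at 0 of 4081 positions by limma, the single tool run, and 359 had an unadjusted p under 0.05. The oxidation effect at sites that the authors list as stringent in 1 stage, 13 procyclic and 22 bloodstream ones, was thus not shown to differ between stages. Without procyclic oxidised replicate 3 the interaction was called at 44 positions, without bloodstream oxidised replicate 3 at 12, and with replicates 1 and 2 alone, chosen after the data were seen, at 550. With replicate 3 as a block, also chosen afterwards, it was called at 3, all with the higher log2 fold change in the bloodstream form.

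The largest interaction among these sites was at position 376981 of LSU beta, which reached 27664, 29223 and 1017 SPM in procyclic oxidised replicates 1, 2 and 3 and 224, 215 and 857 in bloodstream ones. Its interaction log2 value was -5.27 ± 1.35 (SE, limma adjusted p = 0.339), and -7.97 with replicates 1 and 2 alone (adjusted p = 0.00136). Position 375131 of LSU alpha had 4094 ± 1030 against 1528 ± 708 in oxidised libraries (SD, n = 3, interaction -1.96 ± 0.68, limma adjusted p = 0.433). Position 374569, next to the shared site 374570, had 312 ± 110 against 900 ± 302 (interaction 1.59 ± 0.60, limma adjusted p = 0.469). With replicates 1 and 2 alone, the interaction was also called at 375131 (-2.73, adjusted p = 0.00667), 374569 (1.66, adjusted p = 0.0466), 374276 (3.95, adjusted p = 0.0340) and 374318 (2.46, adjusted p = 0.0139). With all replicates, the other 7 of the 10 named sites lay between -1.25 and 2.30, with adjusted p of 0.339 to 0.828.

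Controls showed no called stage difference when all replicates were used. Of 4344 positions, 0 passed the limma threshold and 919 had an unadjusted p under 0.05. Replicates 1 and 2 of each stage were alike and replicate 3 stood apart from them within both stages. Across 2068 positions, the SD of the log2 difference was 0.236 to 0.258 between replicates 1 and 2 of a stage, 0.806 to 0.874 between replicate 3 and its own stage, 0.729 to 0.808 between replicate 3 and replicates 1 and 2 of the other stage, and 0.498 between the replicate 3 libraries of the 2 stages. The largest values, 1.08 to 1.09, were between replicates 1 and 2 of the procyclic form and those of the bloodstream form. Replicate 3 of each stage thus lay nearer to both of these pairs than the pairs lay to each other. With replicates 1 and 2 alone, 2180 positions differed, 1114 higher and 1066 lower in the bloodstream form. Leaving out procyclic control replicate 3 gave 700 calls and leaving out bloodstream control replicate 3 gave 579. The stage difference of replicates 1 and 2 did not recur in replicate 3, with a Pearson r across positions of -0.211 (95% bootstrap interval -0.280 to -0.134), although replicates 1 and 2 matched each other at 0.948. Replicate 3 has 1 library per stage and gave no test of its own.

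In oxidised libraries, 3 of 1793 tested positions differed between stages, and they are named here after their values were seen. Position 373471 of LSU alpha was higher in the bloodstream form (log2 3.86 ± 0.74, SE, limma adjusted p = 0.0231), as was position 372245 of SSU (4.15 ± 0.87, adjusted p = 0.0461). Position 376981 of LSU beta was lower (-4.61 ± 0.86, adjusted p = 0.0231). None of the 3 passed in controls, but there 0 of 4344 positions passed, so this does not show that the differences are particular to oxidised RNA. The fitted log2 differences in controls were 1.06 ± 0.40 at 373471, 0.64 ± 0.38 at 372245 and 0.85 ± 0.45 at 376981 (SE). The first 2 had the same direction as in oxidised libraries and the last the opposite one. Without procyclic oxidised replicate 1 there were 0 calls, with log2 values of 3.60 at 373471, 4.75 at 372245 and -3.83 at 376981 (limma adjusted p = 0.171, 0.0753 and 0.171). Position 376981 also lost its call with total scaling (-4.72, limma adjusted p = 0.307; 3 higher and 0 lower), with the replicate block (-4.61, adjusted p = 0.0926; 5 higher and 0 lower) and with replicate 3 as a block, chosen after the data were seen (-4.61, adjusted p = 0.0669; 7 higher and 0 lower). It did so as well without procyclic oxidised replicate 2 (-3.92, adjusted p = 0.147), without bloodstream oxidised replicate 3 (-5.30, adjusted p = 0.261) and with multiples of 50, chosen after the data were seen (-5.11, adjusted p = 0.494). Positions 373471 and 372245 lost theirs without bloodstream oxidised replicate 1, at log2 values of 3.49 and 3.85 (limma adjusted p = 0.240 and 0.228). Calls numbered 1 without bloodstream oxidised replicate 1, 41 without procyclic oxidised replicate 3, 86 without bloodstream oxidised replicate 3, and 321 with replicates 1 and 2 alone. The stage difference of oxidised replicates 1 and 2 had an r of 0.053 (95% bootstrap interval -0.064 to 0.164) with that of replicate 3 over 538 positions.

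**Figure D3:**
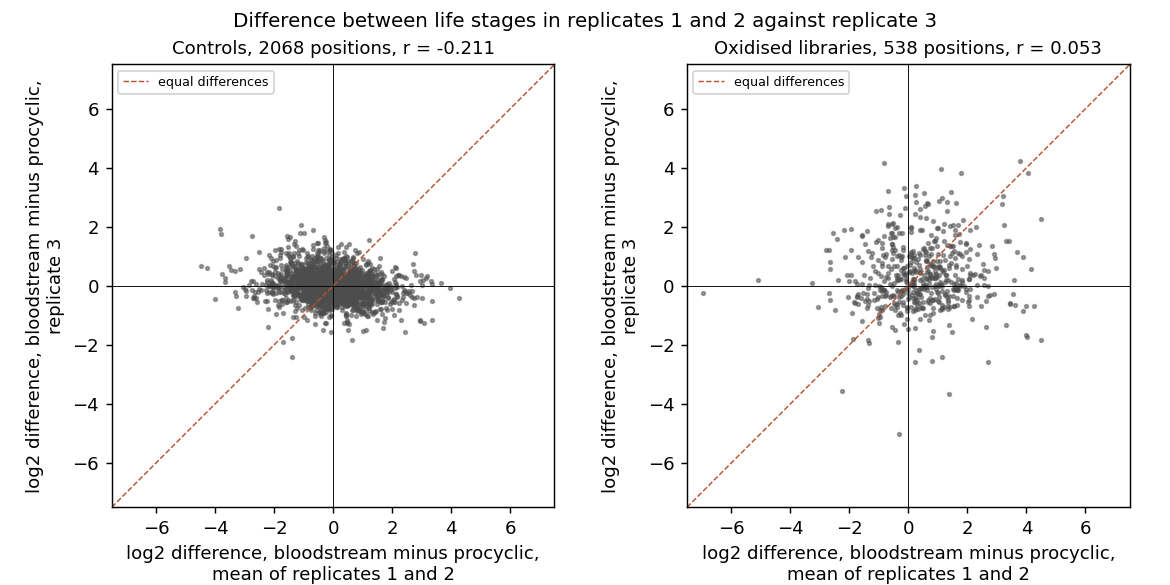
Log2 difference of the SPM plus 10 between bloodstream and procyclic form in replicate 3 (y axis) against the mean of replicates 1 and 2 (x axis), for controls (left, 2068 positions) and oxidised libraries (right, 538 positions), each point 1 position. Points do not follow the dashed line of equal differences, and r is -0.211 in controls and 0.053 in oxidised libraries.

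**Figure D4:**
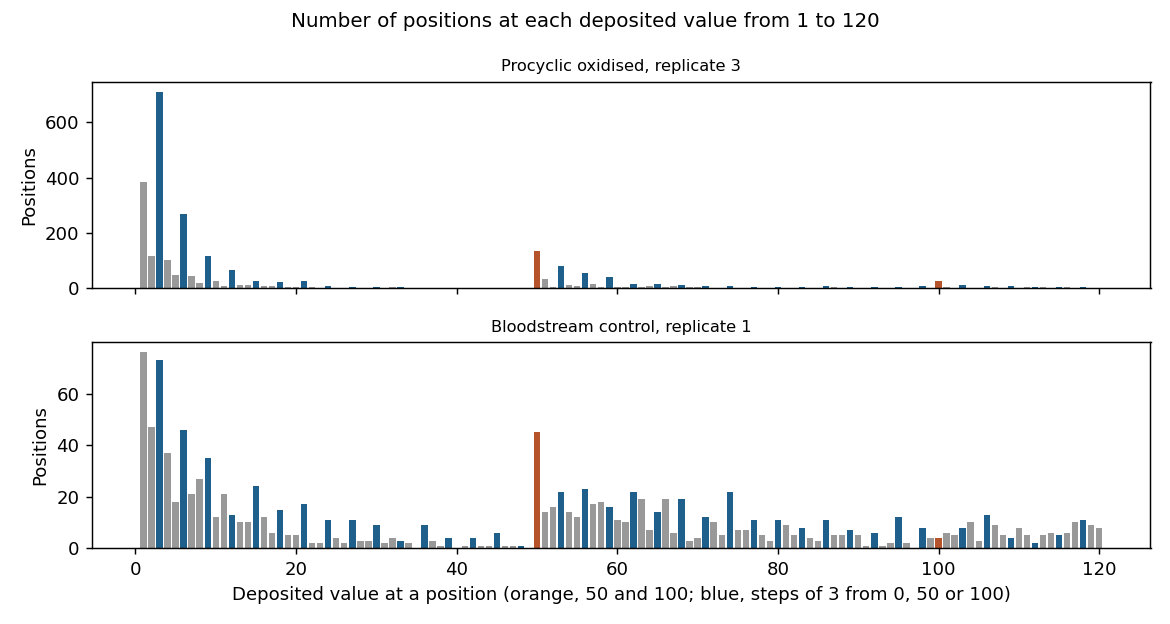
Number of positions (y axis) at each deposited value from 1 to 120 (x axis) in procyclic oxidised replicate 3 (top) and bloodstream control replicate 1 (bottom). In the first of these libraries 135 positions held exactly 50 and 4 held a value from 40 to 49, and steps of 3 stand out at low values.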

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

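All tests of explanations in this part were chosen after the results were seen.

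Controls and oxidised libraries of replicates 1 and 2 showed stage differences that replicate 3 did not show. Life stage alone would give a positive correlation of these differences across positions, and a swap of the replicate 3 labels a slope near -1. The correlation was -0.211 in controls and 0.053 in oxidised libraries, and the slope -0.0984 and 0.0433, so neither explanation was borne out. A preparation batch could place the replicate 3 libraries of both stages near each other, and the SD of log2 differences between them was 0.498 in controls (0.806 to 0.874 to the own stage, 0.729 to 0.808 to replicates 1 and 2 of the other) and 1.161 in oxidised libraries (1.53 to 1.69, 1.43 to 1.84). Between procyclic and bloodstream replicates 1 and 2 it was 1.08 to 1.09 in controls and 1.45 to 1.52 in oxidised libraries. RNA of both stages in replicate 3 was left undecided, since procyclic and bloodstream replicate 3 lay between the stages at 74.2% and 81.2% of differing control positions and at 49.6% and 52.8% of oxidised ones (83.9%, 96.8%, 66.7% and 61.1% among positions of at least 1000 SPM), where over 95% in both stages was asked for, and the labels name no batch.

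The deposited values pile up at 50 and at steps of 3. Sums of weights of 50, 3 and 1 could give this, and all 12 libraries had at least 5 times as many positions at 50 to 59 as at 40 to 49. Reads counted once each, with PCR copies, would give a ratio of at most 2, whereas it was 95.2 in procyclic oxidised replicate 3. No biological explanation was tested.

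Stringent sites on the authors' lists lay in 13 adjacent pairs in the procyclic and 16 in the bloodstream form, against at most 7 and 9 in 10000 random draws. The weaker member was on the 5' side in 84.6% of procyclic pairs (exact binomial p = 0.0225) and 87.5% of bloodstream pairs (exact binomial p = 0.00418). Its score was a median 1.97% and 2.68% of that of the stronger member. The spread of ends of 1 strong site by 1 nucleotide could give this, and so could adjacent methylations of unequal level, which these data do not separate. The binomial tests took pairs as independent, but some share a member, as 374131 with 374132 and 374132 with 374133 do in both stages. Several pairs, such as 370730 with 370731, also occur in both stages. The p-values are therefore a description, and the stages do not test this separately.

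Regrouping the libraries of each comparison left few splits. For the effect of oxidation, 1 of 10 splits had as many calls in the procyclic form (1273, highest other 0) and 1 of 10 in the bloodstream form (1684, highest other 0), and 10 splits are too few for a share under 0.05. The same limit holds for oxidised libraries, with 2 of 10 (3 calls, highest other 3). For controls (10 of 10, highest other 1) and the interaction (100 of 100) the real count by limma was 0, with 919 and 359 positions at an unadjusted p under 0.05. Every split reaches a count of 0, so these shares carry no information. In the interaction split with most calls, 65, the replicate 3 libraries had changed sides.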

How the results depend on the processing

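Alternatives named here as a filter of 100 SPM, treat, a pseudocount, replicate 3 as a block, replicates 1 and 2 alone, multiples of 50 and the positions tested with all libraries were chosen after the data were seen. Named positions kept call and direction wherever they were tested, in 602 procyclic and 609 bloodstream tests, while 73 and 66 further tests were not possible because the position did not pass the filter (with replicates 1 and 2 alone, 6 and 7 of 25 positions were tested). The excess of falls over rises did not hold in every setting: with a filter of 100, rises and falls were 381 and 320 in the procyclic and 522 and 365 in the bloodstream form, and rises were also in excess without any 1 control library. With multiples of 50, rises and falls were 290 and 1416 in the procyclic and 327 and 1918 in the bloodstream form. Of the named interaction values, 8 of 229 tests became calls, and of the 3 positions called in oxidised libraries, 26 of 54 tests lost the call. Called positions in the procyclic form, 1273 in the report, were 3173 with total scaling, 701 with a filter of 100, 774 at adjusted p 0.01 and 651 with treat. In the bloodstream form, 1684 became 3030 with total scaling, 887 with a filter of 100, 1080 with treat, 631 with replicates 1 and 2 alone, and 1041 with runs of adjacent positions counted once. The interaction went from 0 to 3 with replicate 3 as a block, 550 with replicates 1 and 2 alone and 1 with multiples of 50. Stage differences in controls went from 0 to 2180 with replicates 1 and 2 alone. In oxidised libraries, 3 became 0 with no filter, a filter of 100, adjusted p 0.01, treat or a pseudocount of 1, 5 with the replicate block or multiples of 50, 7 with replicate 3 as a block and 321 with replicates 1 and 2 alone. The relaxed lists overlapped at 190 procyclic and 240 bloodstream sites. The 10 highest positions held 51.5% and 9.18% of the procyclic oxidised and control score, and 46.2% and 10.2% of the bloodstream one. Counted as runs, rises numbered 146 in SSU and 121 in LSU alpha in the procyclic form and 204 and 150 in the bloodstream form. On the positions tested with all libraries, calls without procyclic control replicates 1 and 2 were 843 and 845, and falls outnumbered rises without each control in both stages, so that the excess of rises came with the loss of positions from the filter. Leaving out 1 library gave 504 to 1580 calls in the procyclic form (843 to 1774 on the positions tested with all libraries), 744 to 1952 in the bloodstream form (1316 to 2074), 0 to 44 for the interaction, 0 to 700 in controls and 0 to 86 in oxidised libraries. Fewer positions or libraries entered some of these settings; otherwise the cause was not tested. Deviations of control and oxidised libraries of the same number correlated at 0.0646, 0.145 and 0.165 in procyclic and 0.0813, 0.103 and 0.185 in bloodstream replicates 1, 2 and 3. Replicates 2 and 3 of both stages exceeded the threshold of 0.1. The best match was another number for procyclic replicate 1 and bloodstream replicate 2. The labels give both libraries of a number the same passage, so pairs remain possible. The main fits took none, and the replicate block allowed for them. The replicate block gave 1449 procyclic, 1658 bloodstream, 0 interaction and 0 control calls. DESeq2, the filter of 50 reads, glmTreat and the base at each site were not run. Depth as reads is unknown, and 1 weight of 50 is worth 71.3 SPM in procyclic oxidised replicate 3. The filters act on scaled SPM, and the procyclic fit divides the SPM of this library by 0.305. On that scale 1 such weight is above the filter of 20 and also above that of 100.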

Other observations

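The position in this part was chosen after its values were seen. Position 372267 of SSU rRNA, 32 nucleotides before the last scored position, was on both relaxed lists of the authors but on neither stringent list, and held 115805 ± 54964 SPM in procyclic oxidised libraries against 16833 ± 4267 in controls (SD, n = 3). On the scaled values its log2 fold change was 5.32 ± 0.44 (SE, limma adjusted p = 3.12e-05), and 5.26 ± 0.19 in the bloodstream form (limma adjusted p = 1.51e-06). Without the scaling factors the procyclic rise was smaller, as these SPM show.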
